A study of Mus musculus with 5 samples.

How the data were processed

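RNA was measured in the heart ventricles of CD-1 mouse embryos, CD-1 being an outbred strain. Pregnant dams received caffeine at 20 mg/kg or saline vehicle once a day from E6.5 to E9.5, and ventricles were taken at E10.5. Per the labels' protocols, ventricles of embryos that shared dams were pooled and each pool was counted as 1 sample, so the 2 vehicle and 3 caffeine libraries are separate pools. Libraries were made from total RNA with a TruSeq RNA kit and sequenced on an Illumina HiSeq 2000, per the labels. The read length and whether counting used strand are not given in the sources used here.

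The authors deposited 4 tables of estimated counts, which need not be whole numbers: counts per gene and counts per transcript, each on a RefSeq and on an Ensembl release 71 annotation, per the file headers. The submitters' processing notes name TopHat, Partek, mm10 and GRCm38, with no versions. There were 18307 genes on RefSeq, 23245 genes on Ensembl and 25187 transcripts on RefSeq. The deposited estimated counts were not scaled between libraries, and their sums differed between libraries. Reads that match several sequences had to be shared among them by the authors' counting, so counts of overlapping genes, of genes with near-identical copies and of transcripts of 1 gene carry an assignment error that no test below includes. In the deposited RefSeq gene table, 5907 genes with the same start as in the reference annotation had a stop coordinate 1 base past its end. For 249 genes with the same start the end was equal. Ends printed here are therefore the stop minus 1, on mm10.

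The estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr, library sizes were scaled by TMM (factors 0.970 to 1.02), and edgeR 4.0.16 in R 4.3.3 was used for the quasi-likelihood test (glmQLFit with robust = TRUE, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05 (FDR 0.05). The same test was run on RefSeq transcripts. Transcript usage, whether transcripts of 1 gene shift against each other, was tested with edgeR's diffSpliceDGE gene-level F test in genes with several tested transcripts. Unless another tool is named, every adjusted p is from edgeR and every log2 fold change is caffeine minus vehicle, with a standard error (SE) computed as the size of the fold change over the square root of F. CPM values were computed with edgeR from the rounded deposited counts and the TMM-scaled library sizes. The fixed gene lists were tested with limma 3.58.1's camera on the edgeR fit, at a preset correlation of 0.01, adjusted over the 37 lists with at least 5 tested members. Of the 40 lists, the Hox genes and the non-polyadenylated RNAs had too few tested members and the mitochondrially encoded genes none.

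The main tests, the gene lists, the alternatives and the rule for the genes named were set before the data were examined, except where a sentence says otherwise. The rule named the 12 higher and 12 lower genes with the largest change among non-overlapping genes past FDR 0.05 with a mean log2 CPM of at least 1, or all where fewer passed. It also named up to 4 members with the smallest p of each list described and 14 fixed genes given whatever their result. Not all of those members are named, and which of them are was chosen after their values were seen. The fixed genes were Adora1, Adora2a, Adora2b, Adora3, Ryr2, Myh6, Myh7, Nppa, Nkx2-5, Tnni3, Hif1a, Dnmt1, Dnmt3a and Dnmt3b. For transcripts and for transcript usage it named the 5 genes with the smallest p. A gene that the rule takes from the neural list is not reported here.

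The alternatives were RLE, upper-quartile and no scaling, no low-count filter or a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit without robust estimation, the Ensembl tables, the replicate number as a block, leaving out each library in turn, an FDR of 0.1, a fold minimum of 1.2 and the erythroid list as a covariate. For lists, camera with an estimated correlation and fry were run, and for usage the Simes adjustment. Chosen after seeing the data were a per-library spline correction for GC content and transcript length, leaving out Rn45s and Lars2, and the block for transcript usage. GC content and length could be given to 99.2% of RefSeq genes. Ensembl pseudogenes were compared with mitochondrial transcripts with BLAST 2.17.0 at an identity of at least 90% over at least 80% of the length.

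Gene totals lay between 21713381 and 25048134 counts per library, and the common biological coefficient of variation was 0.145. The steps were tested on simulated data drawn from the real means and library sizes, each gene or transcript independently of the others. Each of the gene, transcript and usage steps held 200 changed features. Where fewer features change the adjusted threshold is stricter, so these recovery rates may overstate those of the real comparison. In the gene step on 13829 genes, 25.4% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 10 of 13629 unchanged genes were called. In the transcript step 47.8% of 2-fold changes and 83.3% of 4-fold changes were recovered. In the usage step 141 of 200 genes with a 4-fold shift were recovered, and 11 of 2644 unchanged genes were called. No pair of libraries agreed within counting noise: the chi-square per degree of freedom ran from 11.8 to 42.0, so no library was treated as a repeat of another.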

Results

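The data were gene and transcript counts from 5 RNA libraries of embryonic mouse heart ventricles at E10.5, a stage at which the ventricular wall is forming trabeculae. Dams had been injected daily from E6.5 to E9.5 with caffeine at 20 mg/kg, which blocks adenosine receptors, or with saline vehicle. There were 2 vehicle and 3 caffeine libraries, each a pool of dissected ventricles. RefSeq gene totals were 25048134 and 22397199 counts in vehicle replicates 1 and 2, and 23530555, 23002149 and 21713381 counts in caffeine replicates 1, 2 and 3. The correlation of log2 CPM between libraries, taken across genes, ran from 0.982 to 0.992. Vehicle replicates 1 and 2 correlated at 0.987, and vehicle replicate 2 correlated with caffeine replicate 2 at 0.992. The first principal component held 34.5% of the variance and placed caffeine replicates 1 and 3 at opposite ends, with both vehicle libraries between them. The second (28.2%) placed vehicle replicates 1 and 2 at 30.5 and 0.770 and caffeine replicates 1, 2 and 3 at -7.51, -8.73 and -15.0, setting vehicle replicate 1 furthest apart. On the third (24.4%) the groups overlapped.

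Whether caffeine in early gestation altered gene expression in the embryonic ventricle was asked by comparing the caffeine with the vehicle libraries. Peg3as, a noncoding RNA transcribed opposite to the imprinted gene Peg3, was the only RefSeq gene past FDR 0.05. It fell by 2.24 on the log2 scale (SE 0.21, edgeR adjusted p = 0.00191; limma-voom also passed 1 gene), from 14.1 ± 0.927 CPM in vehicle (SD, n = 2) to 2.97 ± 0.537 CPM in caffeine (SD, n = 3). Its libraries did not overlap: 14.7 and 13.4 CPM in vehicle against 3.57, 2.79 and 2.54 CPM in caffeine. Peg3as lies on chromosome 7 from 6706760 to 6707624 (mm10, plus strand), and all 865 bases lie inside an exon of Peg3, which is on the minus strand (6705960 to 6730419). Its count is therefore uncertain, because reads of the overlapping pair cannot be told apart without strand. Peg3 itself, a maternally imprinted zinc finger gene, had 361 and 745 CPM in vehicle and 599, 620 and 528 CPM in caffeine (log2 fold change 0.08, SE 0.29, adjusted p = 0.999). Of 13829 genes tested, 1 passed FDR 0.05, 0 higher and 1 lower, and 719 had an unadjusted p under 0.05 (433 higher, 286 lower) where 691 would be expected by chance. Libraries of the groups did not overlap for 20.4% of genes, against the 20% that chance gives for 2 against 3. Without vehicle replicate 1 no gene passed, Peg3as having a log2 fold change of -2.18 (SE 0.27) and an adjusted p of 0.105 in a fit with 1 vehicle library (range over the RefSeq alternatives 5.42e-14 to 0.105; the Ensembl tables list no gene of that name, so it could not be examined there), while 8 genes passed without vehicle replicate 2, 18 without caffeine replicate 1 and 2 without caffeine replicate 2.

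**Figure D1:**
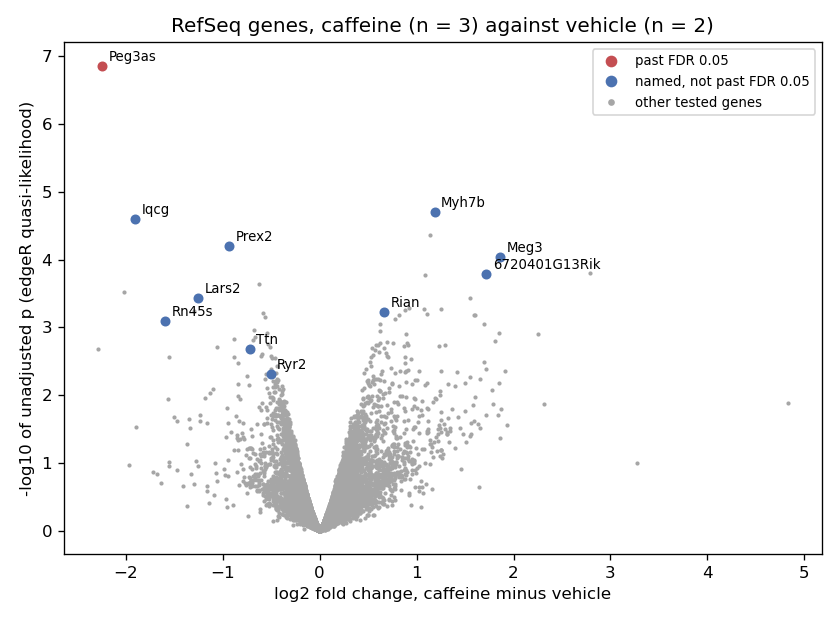
Each point is 1 of 13829 RefSeq genes, with the log2 fold change (caffeine minus vehicle) on the horizontal axis and −log10 of the unadjusted edgeR p on the vertical axis. Peg3as, at -2.24, is the single gene past FDR 0.05, and other labelled genes did not pass.

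DESeq2 called 18 genes on the same counts, 9 higher and 9 lower, and Peg3as was among them. These genes, other than Peg3as, did not pass in the edgeR fit above and were picked after their values were seen. The log2 fold changes and SEs given for them here are those of that edgeR fit, not of DESeq2. With edgeR, Iqcg, Myh7b, Prex2, Raver1-fdx1l and Tmem181b-ps passed with no low-count filter and, like BC090627 and Nipal4, without caffeine replicate 1; Lars2 passed without vehicle replicate 2 and Meg3 without caffeine replicate 2. Higher in caffeine by DESeq2 were Meg3 and Rian, maternally expressed noncoding RNAs of the Dlk1-Dio3 imprinted domain on chromosome 12. Meg3 (109540996 to 109571729, plus strand) had a log2 fold change of 1.86 (SE 0.28; DESeq2 adjusted p = 1.73e-09, edgeR adjusted p = 0.208), from 9.75 ± 3.48 CPM (SD, n = 2) to 35.4 ± 8.53 CPM (SD, n = 3). Rian (109603945 to 109661711) had 0.67 (SE 0.15; DESeq2 adjusted p = 0.0400, edgeR adjusted p = 0.383). The neighbouring Mirg passed with neither tool (1.12, SE 0.40, edgeR adjusted p = 0.899; 0.70 without vehicle replicate 1). Also higher by DESeq2 were the X-linked noncoding RNA 6720401G13Rik (log2 fold change 1.72, SE 0.28), the myosin heavy chain gene Myh7b (1.19, SE 0.18), the pseudogene Tmem181b-ps (1.14, SE 0.18), the snoRNA host gene Snhg5 (1.08, SE 0.20), and BC090627, Leng8 and the read-through gene Raver1-fdx1l. Lower by DESeq2 were Rn45s, the precursor of ribosomal RNA (-1.59, SE 0.28), and Lars2, the mitochondrial leucyl-tRNA synthetase (-1.26, SE 0.22). Iqcg (-1.90, SE 0.29), the Rac exchange factor Prex2 (-0.93, SE 0.16), Nipal4 (-1.30, SE 0.27), the translation initiation factor Eif5b (-0.63, SE 0.12), the chromatin protein Hmgb1 (-0.58, SE 0.13) and Ahnak (-0.57, SE 0.13) were also lower by DESeq2. Counts of Rn45s, of the pseudogene Tmem181b-ps, of the read-through gene and of Hmgb1 are uncertain, because similar or overlapping sequences share their reads. The fall of Prex2 lay in 1 transcript, NM_001033636, with 18.6 CPM in vehicle and 1.94 CPM in caffeine. Its other tested transcript, NM_029525, went from 39.8% to 88.6% of the gene's counts, and Prex2 was among the genes with changed transcript usage. Whether the RNA or the read assignment changed there was not tested. Rn45s took 0.864% and 0.520% of the counts in the vehicle libraries and 0.172%, 0.276% and 0.271% in the caffeine libraries. Lars2 took 0.0471% and 0.0288% in vehicle and 0.0135%, 0.0182% and 0.0180% in caffeine, so the libraries ranked in the same order for both. Whether the Lars2 count holds reads of similar sequences was not tested.

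**Figure D2:**
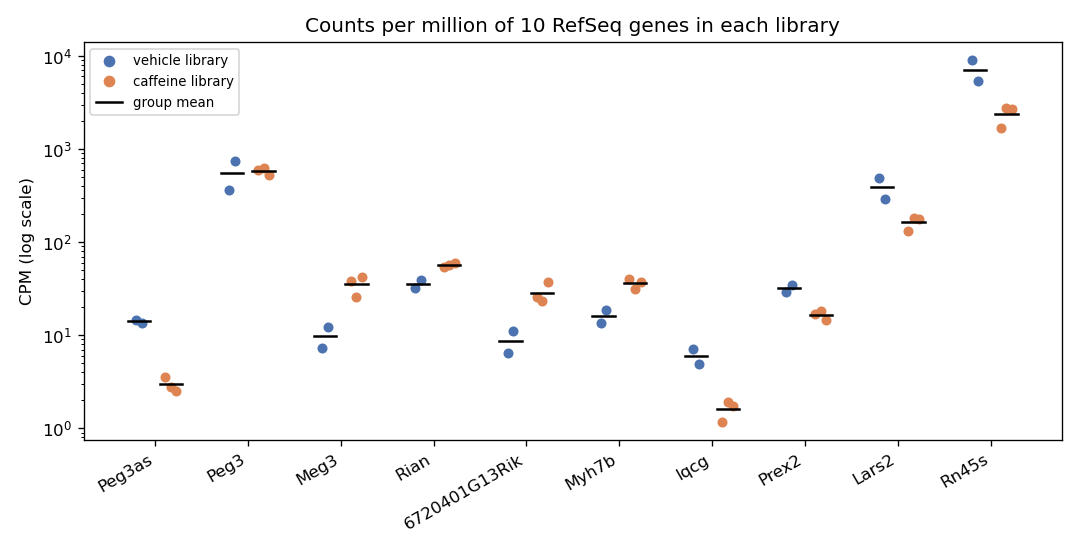
CPM of 10 RefSeq genes (log scale) in the 2 vehicle and 3 caffeine libraries, with a line at each group mean. Peg3as lies at 13.4 CPM or more in vehicle and at 3.57 CPM or less in caffeine, while the Peg3 libraries overlap.

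Among the fixed lists, 7 of 37 passed camera at FDR 0.05, 4 lower and 3 higher in caffeine; with an estimated correlation none held, and fry passed none. Unadjusted, 1 list had a p under 0.05 with an estimated correlation and 2 with fry. The 53 genes of cytosolic ribosomal proteins were lower as a set (median log2 fold change -0.21, camera adjusted p = 1.48e-18; adjusted p = 0.762 with an estimated correlation), with a negative value in 53 of 53. None passed alone, and the members with the smallest p were Rps6 (-0.44, SE 0.12), Rps20 (-0.44, SE 0.13), Rps25 (-0.43, SE 0.13) and Rps27a (-0.46, SE 0.14). Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain. With Ensembl counts, 36 of 51 members were negative, and Rps6 and Rps27a had positive values (0.29 and 0.27), while the list still passed camera (median -0.17, against -0.22 for the same members on RefSeq; camera adjusted p = 1.65e-05). The 29 tested sarcomere genes, which build the contractile apparatus, were also lower as a set (median -0.21, camera adjusted p = 7.82e-11; adjusted p = 0.762 with an estimated correlation), with a negative value in 29 of 29. Their smallest p belonged to the giant scaffold Ttn (-0.72, SE 0.18), followed by the troponin Tnni3 (-0.38, SE 0.14), the tropomyosin Tpm1 (-0.29, SE 0.14) and the troponin Tnnt2 (-0.34, SE 0.16), none past FDR 0.05. Without vehicle replicate 1 Tnni3 had -0.19 and Tpm1 -0.14, without vehicle replicate 2 Ttn had -0.41 and Tnni3 -0.58, and without caffeine replicate 3 Tnnt2 had -0.21. Nuclear genes of oxidative phosphorylation were lower as a set (38 genes, median -0.13, camera adjusted p = 2.05e-06; adjusted p = 0.762 with an estimated correlation), with 33 negative and 5 positive. Cox7b (-0.57, SE 0.17), Uqcrb (-0.40, SE 0.14), Cycs (-0.33, SE 0.14) and Ndufb3 (-0.33, SE 0.15) had the smallest p there.

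These sets rested in part on vehicle replicate 1. The mean log2 CPM of the ribosomal list was 8.67 and 8.36 in the vehicle libraries against 8.32, 8.33 and 8.24 in caffeine, and that of oxidative phosphorylation 8.12 and 7.80 against 7.90, 7.85 and 7.71. For the sarcomere list it was 9.90 and 9.75 against 9.58, 9.63 and 9.59. Without vehicle replicate 1 the ribosomal median was -0.06 (camera adjusted p = 0.130), the oxidative phosphorylation median 0.03 (0.874) and the sarcomere median -0.09 (0.000752). Without it Rps20 and Rps27a had -0.28, Cycs -0.21 and Ndufb3 -0.17. Over the alternatives run the adjusted p ranged from 1.17e-32 to 0.762 for the ribosomal list, from 2.87e-16 to 0.874 for oxidative phosphorylation and from 6.93e-12 to 0.762 for the sarcomere list. Rn45s was also lower in all caffeine libraries than in both vehicle libraries. The ribosomal list and the non-polyadenylated list that holds Rn45s had both been listed as measures of RNA quality. Whether Rn45s and these lists share a cause was not tested.

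Markers of foregut and hepatic endoderm, tissue next to the heart, were lower as a set (13 tested genes, median -1.27, camera adjusted p = 0.00398; adjusted p = 0.762 with an estimated correlation), at low levels. Hnf4a had 0.852 CPM in vehicle and 0.343 CPM in caffeine (log2 fold change -1.27, SE 0.69), and Fga -1.97 (SE 1.04). The list's mean log2 CPM was 0.11 in vehicle replicate 1 and 2.51 in vehicle replicate 2, against 1.21, 0.82 and -0.08 in caffeine, so it followed vehicle replicate 2. Without that library the median was 0.61 (camera adjusted p = 0.0594). Without caffeine replicate 3 it was -0.93 (camera adjusted p = 0.144). Over the alternatives the highest adjusted p was 0.798 with fry, and 0.762 with camera at an estimated correlation. The call was also lost with the GC content and length correction (camera adjusted p = 0.179, against 0.0119 on the same limma-voom values without it), a correction chosen after the result was seen. The median went from -1.27 (SD over members 0.62) to -1.22 (SD 0.61), and the cause of the loss was not tested.

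Immediate early genes, which respond within minutes to stimuli and to dissection, were higher as a set (26 genes, median 0.16, camera adjusted p = 0.00422; adjusted p = 0.762 with an estimated correlation), with 24 positive. Nr4a1 (0.38, SE 0.16), Cyr61 (0.36, SE 0.16), Rhob (0.25, SE 0.13) and Socs3 (0.38, SE 0.21) had the smallest p, and none passed alone; without caffeine replicate 3 Cyr61 had 0.24. The call was lost without vehicle replicate 2 (median 0.07) or caffeine replicate 1 (0.11). With the GC content and length correction, chosen after the result was seen, the median went from 0.16 (SD over members 0.12) to 0.07 (SD 0.13), and the list still passed (camera adjusted p = 0.0281). Embryonic erythroid genes were higher as a set (26 genes, median 0.19, camera adjusted p = 0.00484; adjusted p = 0.762 with an estimated correlation), led by the mitochondrial iron importer Slc25a37 (0.71, SE 0.18), Epb4.2 (0.58, SE 0.23), Ermap (0.38, SE 0.20) and Hemgn (0.36, SE 0.20). Its mean log2 CPM overlapped between groups: 6.17 and 5.66 in vehicle against 6.20, 5.71 and 6.22 in caffeine, and without vehicle replicate 2 the median was -0.07. The call was also lost without caffeine replicate 1 (0.14) or caffeine replicate 3 (0.10). Without vehicle replicate 2 Epb4.2 had 0.24 and Hemgn 0.16, and without caffeine replicate 3 Ermap had 0.20. With the same correction the median of its 25 members with GC values went from 0.21 (SD over members 0.26) to 0.13 (SD 0.22), and the list still passed (camera adjusted p = 0.00351). Circadian clock genes were higher as a set (15 genes, median 0.19, camera adjusted p = 0.0320; adjusted p = 0.762 with an estimated correlation), with Per2 at 0.68 (SE 0.22), Per3 at 0.41 (SE 0.24), Per1 at 0.22 (SE 0.15) and Bhlhe40 at 0.21 (SE 0.15). Without caffeine replicate 1 Per3 had 0.15 and Per1 0.14. Leaving out either vehicle library (0.15 and 0.16) or caffeine replicate 1 (0.14) ended this call, as did Ensembl counts (median 0.19, camera adjusted p = 0.124; range over the alternatives 0.00957 to 0.762). With the GC content and length correction, chosen after the result was seen, the camera adjusted p was 0.0523, against 0.0201 on the same limma-voom values without it. The median went from 0.19 (SD over members 0.19) to 0.14 (SD 0.20), and the causes were not tested.

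**Figure D3:**
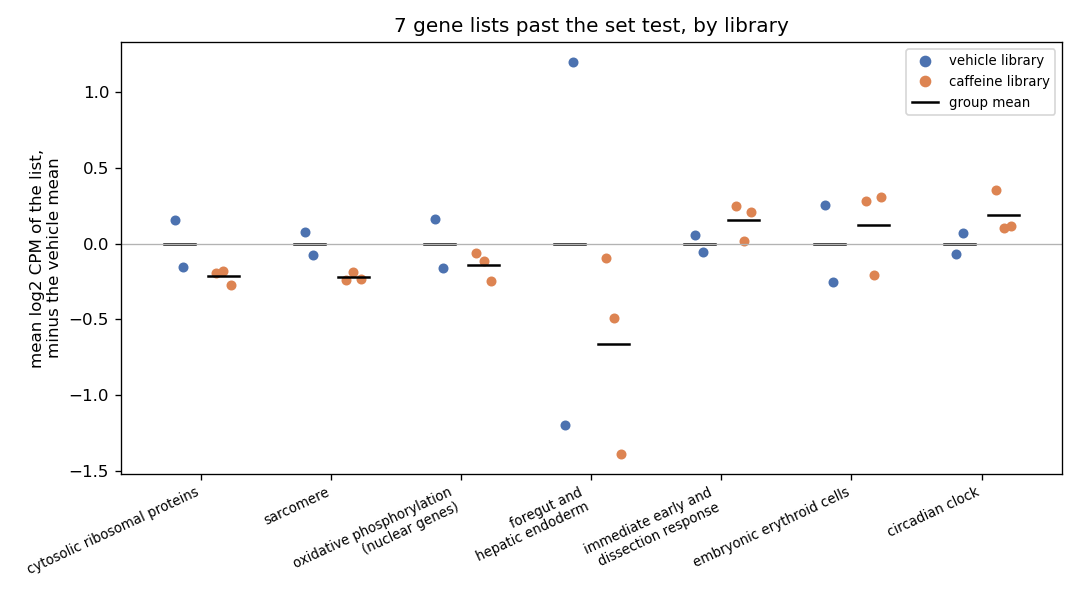
Mean log2 CPM of the members of the 7 lists past camera in each library, minus the mean of the 2 vehicle libraries, with a line at each group mean. The sarcomere, ribosomal and circadian libraries separate by group, while those of the other lists overlap. The lists shown were picked by a test on these same libraries.

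The receptors and enzymes on which caffeine acts did not pass. Adora1, the adenosine A1 receptor gene, had 20.9 ± 0.508 CPM in vehicle (SD, n = 2) and 22.1 ± 4.58 CPM in caffeine (SD, n = 3), a log2 fold change of 0.08 (SE 0.18). Adora2a had a value of 0.16 (SE 0.19), while Adora2b (1 to 6 counts per library) and Adora3 (2 to 5 counts) were too low to test. Adenosine signalling as a list had a median of -0.02 (14 genes, camera adjusted p = 0.708), with Entpd1 at -0.36 (SE 0.15). Phosphodiesterases, cyclases and CREB targets had a median of 0.07 (34 genes, 0.194), with Pde3a at 0.45 (SE 0.19; 0.17 without vehicle replicate 1), and xenobiotic metabolism one of -0.13 (12 genes, 0.482). The ryanodine receptor Ryr2, whose channel caffeine opens, had a log2 fold change of -0.51 (SE 0.15, adjusted p = 0.701), from 435 ± 106 CPM (SD, n = 2) to 306 ± 14.0 CPM (SD, n = 3). Without vehicle replicate 1 it had -0.74, and without vehicle replicate 2 it had -0.26. Its list, calcium handling and conduction, had a median of -0.01 and a mean of 0.0025 (25 genes, 0.561; direction of the test lower).

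Cardiac identity genes did not pass either. Myh6 had a log2 fold change of -0.19 (SE 0.14), Myh7 -0.27 (SE 0.13), Nppa 0.12 (SE 0.14), Nkx2-5 0.13 (SE 0.15) and Hif1a 0.01 (SE 0.14). The DNA methyltransferases had -0.18 (SE 0.14) for Dnmt1, -0.14 (SE 0.13) for Dnmt3a and -0.03 (SE 0.19) for Dnmt3b. Without 1 library Myh6 ran from -0.26 to -0.08, Nppa from 0.02 to 0.21, Dnmt1 from -0.28 to -0.07 and Dnmt3a from -0.26 to -0.04. Of the chromatin modifiers, Mll2 had -0.37 (SE 0.14), Hdac4 0.51 (SE 0.23), Hdac7 0.31 (SE 0.14) and Chd7 -0.28 (SE 0.16), and without 1 library Mll2 ran from -0.54 to -0.19, Hdac4 from 0.18 to 0.89 and Chd7 from -0.51 to -0.05. Cardiac list medians were 0.10 for transcription factors (25 genes, camera adjusted p = 0.0817), 0.01 for working ventricular myocardium, with a mean of -0.02 and a test direction of lower (18 genes, 0.561), 0.10 for atrial and sinus venosus markers (13 genes, 0.987) and 0.05 for outflow tract markers (12 genes, 0.708). Chromatin modifiers had a median of 0.01, though the direction of the test was lower (37 genes, 0.853), and imprinted growth genes one of 0.06 (17 genes, 0.0955). Adjusted over the list alone, Meg3 (adjusted p = 0.00153) and Rian (adjusted p = 0.00508) of the imprinted list passed, and Rn45s (0.00162) and Rmrp (0.00211), the only tested members of the non-polyadenylated list. Over all genes none of these 4 passed, and no other list had a member that passed adjusted over the list alone.

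The growth and stress lists not given above did not pass camera. Cell cycle genes had a median of -0.05 (39 genes, camera adjusted p = 0.0565), with the kinetochore genes Cenpf at -0.52 (SE 0.17) and Cenpe at -0.51 (SE 0.17) and Mki67 at -0.35 (SE 0.15). Without vehicle replicate 2 these had -0.24, -0.25 and -0.13. Hypoxia and glycolysis had a median of 0.01 with a test direction of lower (37 genes, 0.675), and Vegfa at 0.45 (SE 0.13) and Pgk1 at -0.32 (SE 0.13). The heat shock list had a median of -0.04 (27 genes, 0.231), with Hsp90aa1 at -0.40 (SE 0.14), Hspd1 at -0.38 (SE 0.14), Atf4 at 0.36 (SE 0.14) and Hspa1a at 0.76 (SE 0.32). Targets of p53 had a median of 0.07 (30 genes, 0.303), led by Gadd45g (0.54, SE 0.17) and Bbc3 (0.53, SE 0.22). Glucocorticoid response genes had 0.04 (18 genes, 0.665), replication-dependent histones -0.28 (9 genes, 0.0704) and fatty acid metabolism 0.01 with a test direction of lower (29 genes, 0.853). Signalling medians were 0.13 for Wnt and FGF (32 genes, 0.267), 0.07 for BMP and TGF-beta (33 genes, 0.267), 0.05 for Notch and trabeculation (26 genes, 0.641) and 0.09 for retinoic acid (17 genes, 0.593). Fgfr3 had 0.69 (SE 0.26), Wnt5a 0.43 (SE 0.17) and Spry1 0.44 (SE 0.18). Without vehicle replicate 1 these had 0.37, 0.18 and 0.28, and Hspa1a had 0.48, while without vehicle replicate 2 Bbc3 had 0.31. The extracellular matrix median was -0.02 and its mean 0.07 (43 genes, 0.739).

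Other cell types in the pools were followed by their markers, none of whose lists below passed. Endothelial genes had a median of -0.05 (28 genes, camera adjusted p = 0.383), cushion mesenchyme 0.08 (23 genes, 0.482), epicardium 0.17 (18 genes, 0.118) and macrophages and other blood cells 0.17 (21 genes, 0.482). Egfl7 had 0.45 (SE 0.15), Vwf -0.29 (SE 0.13), Msln 1.22 (SE 0.52), Wt1 0.30 (SE 0.15), Krt19 -0.36 (SE 0.19), C1qb 1.56 (SE 0.61), Itgam 1.14 (SE 0.53) and Pf4 -0.75 (SE 0.34). Neural genes had a median of 0.13 (9 genes, 0.561), somite and skeletal muscle -0.31 (7 genes, 0.0565) and yolk sac, placenta and maternal tissue -0.77 (11 genes, 0.767). Tnnt3 had -0.83 (SE 0.32), Tnni2 -0.58 (SE 0.23), Prap1 1.71 (SE 0.63), Prl8a2 1.66 (SE 0.67) and Apom -1.56 (SE 0.83). The largest of these changes were at low levels and rest on few counts. Mean CPM in vehicle and caffeine was 0.475 and 1.11 for Msln, 0.304 and 0.902 for C1qb and 0.237 and 0.530 for Itgam. It was 0.334 and 1.14 for Prap1, 0.297 and 0.957 for Prl8a2 and 1.08 and 0.356 for Apom. Without 1 library Egfl7 ran from 0.26 to 0.63, Msln from 0.61 to 1.47, Wt1 from 0.15 to 0.44, Krt19 from -0.49 to -0.18, Pf4 from -1.15 to -0.23, Tnnt3 from -1.10 to -0.54, Tnni2 from -0.80 to -0.35, Prap1 from 0.94 to 3.56 and Apom from -2.43 to 0.76. The sex-linked list had a median of -0.21 and a mean of -0.08 (5 genes, 0.316). Xist, expressed from the inactive X of females, was at 12.3 and 90.7 CPM in vehicle and 57.7, 117 and 121 CPM in caffeine, and the Y-linked Eif2s3y at 50.5 and 27.0 CPM against 35.6, 17.4 and 20.3 CPM, so the pools differed in their mix of sexes. The 4 tested Hox genes had a median of 0.18 and no set test.

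At the level of RefSeq transcripts, none of 18418 passed FDR 0.05 with edgeR, while 1355 had an unadjusted p under 0.05 (708 higher, 647 lower). The smallest p belonged to Peg3as, which has a single transcript, and to single transcripts of Stox2 (log2 fold change -1.84, SE 0.20), of the glycolytic enzyme Aldoa (-2.45, SE 0.27), of Dpysl3 (1.28, SE 0.15) and of G3bp2 (-1.09, SE 0.14), each with an adjusted p of 0.149.

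Transcript usage separated the groups in 89 of 2897 genes with several tested transcripts (edgeR diffSpliceDGE), and 512 genes had an unadjusted p under 0.05. The most such genes from any other split of the libraries was 366. Aldoa had the smallest adjusted p (0.00041): its transcript NM_001177308 held 9.92% ± 2.24 of the gene's counts in vehicle (SD, n = 2) and 1.92% ± 0.790 in caffeine (SD, n = 3). For Hdac7, a class II histone deacetylase gene (adjusted p = 0.00041), NM_019572 went from 39.2% ± 1.499 to 61.2% ± 3.25 (SD, n = 2 and 3). For Snap23, a membrane fusion protein gene (adjusted p = 0.00162), NM_001177793 went from 50.05% ± 8.02 to 15.7% ± 3.24 and NM_009222 from 44.0% ± 5.90 to 72.2% ± 5.38. NM_011740 of Ywhaz, a 14-3-3 protein gene (adjusted p = 0.00162), went from 5.71% ± 0.426 to 12.2% ± 0.721. NM_001159751 of Tcea1, a transcription elongation factor gene (adjusted p = 0.00310), went from 29.0% ± 4.56 to 10.4% ± 2.11. In each of these transcripts every caffeine library lay on 1 side of both vehicle libraries. They come from the genes with the smallest p in the same libraries, so this separation adds no support. Some other transcripts of these genes overlapped between groups, such as NM_001177307 of Aldoa. The shares of transcripts that overlap over most of their length carry read assignment error. Without vehicle replicate 1 the adjusted p was 0.0743 for Hdac7 and 0.0513 for Ywhaz, and without vehicle replicate 2 it was 0.0561 for Tcea1, so these calls were lost; with Simes it was 0.0521 for Hdac7. Over Simes and the fits that left out 1 library, the adjusted p ranged from 0.00438 to 0.0743 for Hdac7, from 0.00222 to 0.0513 for Ywhaz and from 0.00775 to 0.0561 for Tcea1. The number of genes fell to 28 with the Simes adjustment, all of them among the 89. Without caffeine replicates 1, 2 and 3 it was 35, 46 and 49, of which 23, 39 and 35 were among the 89. Leaving out a vehicle library, which leaves 1, also changed which genes passed. With Ensembl transcripts 523 genes passed, and 42 of them were among the 89 by name.

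**Figure D4:**
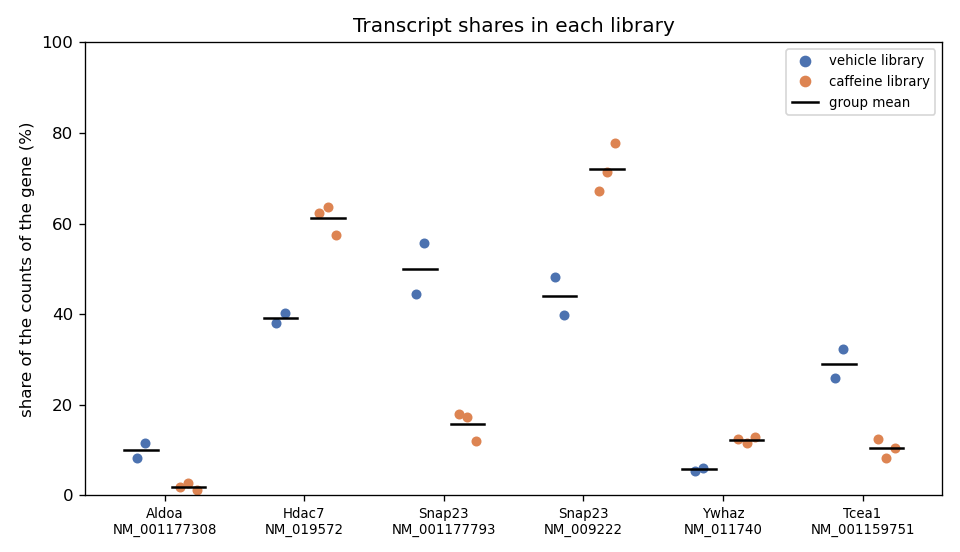
Share of the counts of a gene held by 6 transcripts of Aldoa, Hdac7, Snap23, Ywhaz and Tcea1 in each library (percent), with a line at each group mean. The caffeine libraries lie apart from the vehicle libraries in all 6, which come from the genes with the smallest p in these same libraries.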

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

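The GC content and length correction, camera on limma-voom values, leaving out Rn45s and Lars2, and the block for usage were chosen after the result was seen. The count of genes was 1 with RLE, upper-quartile or no scaling, a 5 CPM filter, limma-voom, no robust estimation, an FDR of 0.1, a 1.2-fold minimum, the erythroid covariate and without Rn45s and Lars2. It was 6 with no low-count filter, 18 with DESeq2 and 2 with Ensembl counts, and the cause was not tested; with the GC content and length correction it was 0, because Peg3as had no GC value and was not tested. Without 1 library it ran from 0 to 18. The lists past the set test numbered 0 with an estimated correlation, 0 with fry, 11 with camera on limma-voom values, 5 with the GC content and length correction of those values, and 8 to 12 without 1 library, the 12 being without caffeine replicate 2. Changed transcripts numbered 0 to 1 without 1 library. Genes with changed usage numbered 28 with Simes, 523 of 7540 with Ensembl transcripts and 15 to 53 without 1 library; the 15 genes without vehicle replicate 1 shared 8 with the 89. Dropping a vehicle library leaves 1, assumed to vary like the caffeine libraries.

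The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.02 and 0.13. With the replicate block, genes numbered 52, among them Ttn and the genes called by DESeq2 other than Rian, Eif5b, Hmgb1 and Ahnak. With this block lists numbered 12, transcripts 9 and usage genes 3, Adora1 had a log2 fold change of -0.10, and the cause was not tested. There the erythroid list, of the 7 called, was not called (median 0.11, camera adjusted p = 0.701), and for usage the adjusted p was 0.0388 for Aldoa, 0.0760 for Snap23, 0.1004 for Hdac7 and Ywhaz and 0.141 for Tcea1.

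Over the 93 genes named and tested, 1207 of the other fits kept direction and side of the threshold, 46 newly passed, 1 (Peg3as without vehicle replicate 1) no longer passed and 19 reversed, none of these called. Only Peg3as passed in the main fit, so keeping the side of the threshold mostly meant not passing again. Genes called by DESeq2 were named because of that call, so their passing with DESeq2 was fixed in advance. This tally is therefore no measure of how firm the results are. Of the values that reversed, Peg3 had -0.13, Rps6 0.29 and Rps27a 0.27 in the Ensembl table. Hif1a had -0.0019 with RLE and -0.0030 with DESeq2, and Dnmt3b 0.029 without scaling. Without 1 library, 51 of the 93 moved over 1.5 times or turned. Peg3 ran from -0.36 to 0.66, Adora1 from -0.10 to 0.18, Adora2a from -0.020 to 0.33, Nkx2-5 from -0.023 to 0.28, Hif1a from -0.13 to 0.13, Dnmt3b from -0.21 to 0.14, Hnf4a from -2.06 to 0.44, Fga from -2.91 to 1.23 and Apom from -2.43 to 0.76. List medians ran from -0.066 to 0.50 for erythroid genes, from -2.03 to 0.61 for endoderm from -0.33 to 0.030 for oxidative phosphorylation, from -0.39 to -0.063 for ribosomal, from -0.34 to -0.087 for sarcomere and from 0.074 to 0.29 for immediate early genes. The causes were not tested. With 2 vehicle libraries, most 1.5-fold changes would be missed, as 25.4% were recovered in a simulation with 200 changed genes. Fewer may be recovered where fewer genes change.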

Other observations

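The tests of read sharing, of Peg3as, of vehicle replicate 1, of blood cells and of other splits and the GC content and length correction were chosen only after the result was seen, while the bounds for transcript length and for the GC trend were written before their values were seen. In the Ensembl gene table, 5 pseudogenes that match mitochondrial genes at 92.3% to 100% identity were all lower in caffeine. Gm13341, a copy of mt-Co2, fell by 1.69 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0287), from 1710 ± 15.4 CPM in vehicle (SD, n = 2) to 531 ± 138 CPM in caffeine (SD, n = 3). Gm13340, a copy of mt-Co1, had -1.62 (SE 0.28), Gm13339 (mt-Nd2) -1.25 (SE 0.16), Gm11407 (mt-Nd5) -1.90 (SE 0.29) and Gm10222 (mt-Nd4l) -1.12 (SE 0.33), none past FDR 0.05. These counts are uncertain because reads of mitochondrial transcripts can match the copies, and mitochondrial genes themselves were not analysed here. Gm14287 was the other Ensembl gene past FDR 0.05 (adjusted p = 0.00334), with 3.50 and 2.99 CPM in vehicle and 0 CPM in the 3 caffeine libraries, where a count of 0 allows up to 3 counts per library. Of 1129 pseudogenes tested, 171 had an unadjusted p under 0.05 in the comparison, 125 lower and 46 higher in caffeine.

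Transcript usage changed in 89 genes, where the highest of the other 9 splits of the 5 libraries gave 0. Of the 10 splits only the real one gave as many, and 10 splits are too few for a share under 0.05. Transcript lengths were medians over the GENCODE transcripts linked to each RefSeq transcript, so they may differ from the transcript counted. The transcript that gained most in caffeine was longer than the one that lost most in 77.8% of the 81 genes with assigned, unequal lengths. The 95% exact interval was 67.2% to 86.3%. Among 1980 genes with a p of 0.05 or more the share was 55.3% (Fisher's exact p = 5.01e-05). The interval and this p treat genes as independent, though all come from the same 5 libraries, so they do not measure variation between libraries. A difference between the groups in fragment length or coverage is therefore a candidate explanation, and so is a difference in how reads were shared among similar sequences: pseudogenes had a p under 0.05 in 15.1% of cases, 2.72 times as often as other genes of matched expression. That comparison was designed after the shares by split had been seen, and 2.72 lies only just above the 2.57 of another split, so it is weak evidence. A change of splicing by caffeine stays open and was not tested apart from these, and the labels give no batch to examine.

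The fall of Peg3as was not a fixed share of Peg3 reads counted on the opposite gene, because its share of both genes' counts had a log2 change of -2.38, from 3.92% and 1.77% in vehicle to 0.594%, 0.451% and 0.481% in caffeine. Read assignment that varied between libraries cannot be told apart from a change of the RNA, because 100% of its bases lie in a Peg3 exon and the use of strand is not given in the sources used here. For the count of genes past FDR 0.05, 3 of the 10 splits, the real split among them, gave at least the 1 gene of the real split. With 10 splits a share under 0.05 cannot be reached. The highest other, which set caffeine replicates 2 and 3 apart, gave 5. At an unadjusted p under 0.05 the real split gave 719 genes, and the most from any other was 1253, with vehicle replicate 1 and caffeine replicate 3 set apart.

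The ribosomal, oxidative phosphorylation and sarcomere lists together had a median log2 fold change of -0.20 over 120 genes. A larger share of blood cells in caffeine was left undecided. The 5 most abundant erythroid genes went both ways (-0.24 to 0.23, mean 0.0087), and for all 5 the libraries of the groups overlapped. The rule written for this test counted overlap in most of the 5 against such a share, but its reading was changed to undecided after the value was seen. In the erythroid list 22 of 26 genes were positive (median 0.19, camera adjusted p = 0.00484, and adjusted p = 0.762 with an estimated correlation). With a correction for GC content and length the joint median was -0.13, 68.6% of its size, between the bounds set beforehand for and against such a trend; by list it went from -0.21 to -0.20 for sarcomere, from -0.21 to -0.15 for ribosomal and from -0.13 to -0.10 for oxidative phosphorylation genes. That all 3 lists still passed camera with the preset correlation (adjusted p = 3.46e-09, 2.14e-09 and 0.0196) argues against the trend as the whole cause, but this criterion was added after the value was seen, and with an estimated correlation none of the 3 passed even without the correction (adjusted p = 0.762 each). Vehicle replicate 1 alone may account for the ribosomal and oxidative phosphorylation lists, whose joint median went from -0.19 to -0.013 without it, whereas the sarcomere list, tested apart only after the values were seen, had -0.087 and still passed camera with the preset correlation (adjusted p = 0.000752; adjusted p = 0.762 with an estimated correlation in all 5 libraries), so part of it stays open, with caffeine among the untested causes.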
